A study of Mus musculus with 3 samples.

How the data were processed

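CD45+ cells of the small intestine were sorted from C57BL/6 mice of 4 genotypes (WT, Bmal1-/-, Apc+/- and Dko), marked with multiplexing oligos, pooled into 3 libraries and sequenced with 10x 3′ v3.1 chemistry. Per the submitters' processing notes, the authors ran Cell Ranger 6.1.2 on the mm10 reference, and per the series description they analysed the cells with Seurat; no Seurat object was used here. The deposited matrices hold counts, that is raw unique molecular identifiers (UMIs) per cell, for 32285 genes and 12 oligo features. All values were whole numbers. The labels give 3 mice per genotype and 1 oligo per genotype in each library, which makes 12 matrices, and they do not say in so many words that a library holds 1 mouse per genotype, nor give sex, time of day or the cells that carry the deletions. Each sample label covers all 4 genotypes of a library, so the genotype of a matrix was read from the genotype name that its deposited file carries. In every matrix 1 oligo took 95.2% to 97.6% of oligo counts, and only 1 of the kept cells had another oligo on top. Oligo counts, 25.5% to 57.0% of all UMIs in a matrix, were kept out of gene totals.

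Of 17983 barcodes, 17700 with at least 200 genes and at most 20% mitochondrial counts were kept. Kept cells held 166265702 gene counts in all, 6532137 to 20103273 per matrix, with a median per matrix of 1549 to 2063.5 genes per cell. The stricter filter (500 genes, 10%) left 17425. Scrublet scores from scanpy 1.11.5 called 33 cells (0.186%) at their own threshold, which is too few for such a load, so the caller did not work here and no call was used; instead the 5% of cells with the highest scores in each library were left out as an alternative. Counts were scaled per cell and logged, 2000 variable genes gave 30 principal components, and cells were joined over 15 neighbours and clustered with Leiden (leidenalg 0.10.2, resolution 1.0, with 0.5 and 2.0 as alternatives, seed 1), without integration. This gave 22 clusters. Other versions were Python 3.11.15, anndata 0.12.19, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

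Clusters were named from markers of 25 types: a type needed 3 markers detected in 10% of cells and higher than in the median cluster by a log2 fold of 1. A cluster stayed unnamed where its 10 leading genes held as many markers of another class as of its best type's class, or were led by proliferation genes. CD8 T cells, γδ T cells and natural killer cells were joined as cytotoxic lymphocytes, and 10 classes were named. Clusters 9, 17, 18 and 21 stayed unnamed. Cluster 9, led by proliferation genes, held on average 1.39%, 1.48%, 3.42% and 2.04% of cells in WT, Bmal1-/-, Apc+/- and Dko. Cluster 18, led by Lef1 and Tcf7, held 5.04%, 10.7%, 1.97% and 1.12%, cluster 17 held 0.986%, 0.608%, 0.811% and 0.935%, and cluster 21, a mix of epithelial and neutrophil genes, 0.02%, 0.189%, 0.229% and 0.701%.

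Counts were summed per matrix over all cells and within each class. The planned classes had at least 20 cells in each matrix: B cells, CD4 T cells and cytotoxic lymphocytes. Monocytes and macrophages, and plasma cells, with at least 10 cells in each matrix, were added after cell numbers had been seen, as was a comparison of neutrophils over the 6 Apc+/- and Dko matrices. Genes were tested with edgeR 4.0.16 (R 4.3.3): filterByExpr, TMM scaling, and a robust quasi-likelihood fit with terms for genotype and library. The 5 contrasts were Bmal1-/- against WT, Apc+/- against WT, Dko against Apc+/-, Dko against WT and the interaction. Adjusted p means Benjamini-Hochberg over the genes of 1 class and contrast, with a threshold of 0.05. Immunoglobulin, T cell receptor, ribosomal and mitochondrial genes stayed in the fits and were left out of the picking of named genes, Igha being the 1 that is named. DESeq2 1.42.0 and limma 3.58.1 (voom) were run beside it. The library was a block because the labels pool the genotypes in it: after each gene was centred on its genotype mean, the 18 pairs of matrices within a library correlated across genes at a mean r of 0.20 (-0.17 to 0.57), and 36 pairs from different libraries at -0.10. The centring ties the latter value to the former, so it is not a separate comparison. Genes are not independent replicates.

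Class shares, in percent of kept cells, were compared by exact two-sided permutation of genotypes within libraries, adjusted over 10 classes. A separate edgeR fit on cell counts was an alternative. Shares of a cluster within a class pool the cells of a genotype over its 3 libraries. The 20 gene lists, 287 genes in all, were tested with camera at a preset correlation of 0.01 and again with an estimated one, and their members were adjusted over the list alone beside the adjustment over all genes. The lists were core clock and output, immune checkpoint, suppressive myeloid, neutrophil granule and chemotaxis, inflammatory cytokine and chemokine, cytotoxic effector, type 3 cytokine, regulatory T, interferon response, MHC class II, T cell naive and memory, T cell tissue residence, glucocorticoid response, dissociation and immediate early, proliferation, plasma cell secretory, oxidative phosphorylation, glycolysis and hypoxia, epithelial background and red cell background. Named genes were, per contrast, up to 15 pairs of gene and class that passed with 1 direction in all 3 libraries and a log2 fold change of at least 0.5 (where fewer than 5 did, also the 5 others of smallest p), up to 10 list members that passed adjusted over the list alone, and a fixed set of genes. A further set was picked after its values had been seen and is said to be so where it is used. CPM are counts per 1e+06 gene counts of a matrix or class, and those of named genes carry the TMM scaling. Those of genes near the targeted loci are unscaled. Gene positions came from GENCODE vM21 (GRCm38), which held 32158 of the 32285 gene identifiers (99.6%).

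The lists, markers, filters, cluster resolution, contrasts and first set of alternatives were fixed before the data were examined. The rule for naming clusters and the joining of classes were revised once after cell numbers per genotype had been seen, and 1 exploratory edgeR fit over all cells had been seen by then. Chosen after seeing the data were also a term for sex, leaving out the WT matrix of library 1, shares without neutrophils, sums without neutrophil and plasma clusters, and edgeR fits within single clusters of a class over the genotypes with at least 10 cells of the cluster in each matrix. Clusters 13 and 14 were fitted with fewer, and the test in cluster 13 was set before its result was seen. By Xist and Y-linked counts library 1 held only females, library 2 only males, and library 3 females of WT and Bmal1-/- and males of Apc+/- and Dko, so that sex and the Apc allele were confounded there.

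The gene fits were tested on counts simulated at the size and spread of the data. Planted 4-fold changes of Dko against WT were found in 66% of cases over all cells, 90% in B cells, 88% in CD4 T cells, 70% in cytotoxic lymphocytes and 85% in monocytes and macrophages; 2-fold changes were found in 18%, 60%, 35%, 24% and 20%. False calls made up 1.15% to 11.84% of calls. The share test was run on simulated values with a set SD of 4, at an unadjusted p under 0.05. It called 5.8% of runs without a difference and 99.8% with one of 15 points. Real shares spread more widely, as with an SD of 22.0 for B cells of WT, and were judged after adjustment. Its power there was not measured. UMIs in a cell type can come from free RNA of other cells of the same pool, and precision is limited by 3 matrices per genotype and, within classes, by as few as 10 plasma cells, 13 monocytes and macrophages or 15 compared neutrophils in a matrix.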

Results

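Immune cells carrying CD45, the surface protein common to leukocytes, were sorted from small intestines of C57BL/6 mice, and their RNA was counted cell by cell with 3′ droplet sequencing. The mice were of 4 genotypes, given here by the names in the labels: WT, Bmal1-/-, Apc+/- and Dko, which joins both alleles. Bmal1, listed under its gene symbol Arntl, encodes a core transcription factor of the circadian clock. Apc encodes a negative regulator of Wnt signalling whose loss starts intestinal tumours. The study asks how disturbing the clock in the intestine alters the immune cells around colorectal tumours. The labels give 3 mice per genotype and 3 pooled libraries, each of which held all 4 genotypes, so that 12 matrices were compared and n was 3 for every genotype. After filtering, 17700 cells remained, 4610 from WT, 5543 from Bmal1-/-, 4088 from Apc+/- and 3459 from Dko. A matrix held 724 to 2322 cells and 6532137 to 20103273 gene counts in unique molecular identifiers, with a median of 4705 to 8630 counts per cell.

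The targeted genes were examined first. Arntl (ENSMUSG00000055116, chromosome 7, 113207465 to 113314126, build GRCm38) had 13.2 CPM (counts scaled to the total of the matrix, as defined under processing) in WT, 11.7 in Bmal1-/-, 12.1 in Apc+/- and 7.68 in Dko over all cells. Its log2 fold change was -0.17 ± 0.19 (SE) in Bmal1-/- against WT (adjusted p = 1.0) and -0.65 ± 0.19 in Dko against Apc+/- (adjusted p = 0.0826), lower in 3 of 3 libraries in both. Arntl fell by 0.78 on the log2 scale in Dko against WT (adjusted p = 0.0232, lower in 3 of 3 libraries). This call ended without replicate 1 (adjusted p = 0.0877), without replicate 3 (0.303), without WT replicate 1 (0.0537), with sex as a term (0.0849) and with only the 2 genotypes compared (0.0749). With neutrophil and plasma clusters left out it was -0.38 (0.171). Within B cells the same contrast gave -0.37 ± 0.29 (adjusted p = 0.714). Apc (ENSMUSG00000005871, chromosome 18, 34220924 to 34322552) had a log2 fold change of 0.32 ± 0.10 in Apc+/- against WT (adjusted p = 0.306, higher in 3 of 3 libraries). In Dko against WT it was 0.40 ± 0.10 (adjusted p = 0.0234, higher in 3 of 3 libraries), which ended without replicate 1 (adjusted p = 0.0911), without replicate 2 (0.0569), without replicate 3 (0.314) and without WT replicate 1 (0.054). That direction rested on the scaling, since unscaled Apc CPM were 38.8, 46.3 and 41.0 in Dko and 50.5, 45.7 and 46.0 in WT. Within classes, Apc itself was among the genes called in Apc+/- against WT. In B cells its unscaled CPM were 69.7, 63.0 and 76.7 in Apc+/- libraries 1, 2 and 3 against 44.0, 51.6 and 51.1 in WT. The scaling added 0.57 to every log2 fold change of Dko against WT and 0.51 to those of Dko against Apc+/- over all cells, and 0.43 and 0.61 in plasma cells. Tags from the 3′ end lie outside the part that such alleles usually delete, and the labels do not say which cells carry the deletions, so these values check neither allele.

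None of 4 clock output genes passed with Bmal1 loss alone. In Bmal1-/- against WT over all cells, Nr1d1, a repressor that Bmal1 activates, was at 0.781 against 1.99 CPM (log2 fold change -1.49 ± 0.72, adjusted p = 1.0, lower in 3 of 3 libraries). Dbp, another direct target, was at 0.18 ± 0.23, Per1 at 0.27 ± 0.14 and Per2 at 0.02 ± 0.36, each with an adjusted p of 1.0. Per1, a repressor of the clock that glucocorticoids also induce, rose by 0.88 ± 0.14 in Dko against WT (adjusted p = 0.00681, higher in 3 of 3 libraries; 0.236 without replicate 3). With neutrophil and plasma clusters left out the rise was 0.42 (adjusted p = 0.0743). Neutrophils of Dko had 115 unscaled CPM of Per1 against 33.9 in B cells of WT, so that the rise was not separated from the composition.

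The cell composition of the sorted fraction was compared between genotypes. Neutrophils, short-lived phagocytes that enter tissue during inflammation, made up 0.175% ± 0.010 (SD) of cells in WT and 0.594% ± 0.582 in Bmal1-/-, against 10.7% ± 8.43 in Apc+/- and 26.2% ± 7.09 in Dko. B cells made up 57.7% ± 22.0 in WT, 63.1% ± 13.2 in Bmal1-/-, 47.4% ± 9.66 in Apc+/- and 14.8% ± 17.4 in Dko. Plasma cells, the antibody-secreting end stage of B cells, made up 1.11% ± 0.394, 1.45% ± 0.942, 2.61% ± 1.54 and 14.1% ± 8.34 in the same order, and monocytes and macrophages 2.60% ± 0.591, 3.34% ± 2.82, 4.08% ± 4.79 and 10.9% ± 9.82. CD4 T cells took 6.35% ± 0.681 in WT and 11.6% ± 5.32 in Dko, and cytotoxic lymphocytes 51.2%, 2.18% and 10.8% in WT libraries 1, 2 and 3. Averaged over the Bmal1 states, the Apc allele went with 18.05 points more neutrophils (exact two-sided permutation within libraries, p = 0.00926, the smallest it can give; adjusted p = 0.0556), 29.3 points fewer B cells (effect -29.3, p = 0.0278, adjusted p = 0.0556) and 7.09 points more plasma cells (p = 0.0278, adjusted p = 0.0556). Each of these averages held its direction in 3 of 3 libraries. In library 1, however, Apc+/- minus WT alone was 23.3 points for B cells and -0.302 for plasma cells. None of the 10 named classes passed 0.05 after adjustment. A lone class at the smallest possible p could not have passed it, so this is no evidence of equal shares. With B cells, plasma cells and non-immune cells left out of the total, 4 classes passed, neutrophils among them with 28.6 points. edgeR on the cell counts of each class called 6 of them for the Apc allele, with log2 fold changes of 5.69 for neutrophils, 3.87 for mast cells and basophils, 2.32 for plasma cells, 1.60 for group 2 innate lymphoid cells, -1.35 for B cells and 1.36 for dendritic cells.

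**Figure D1:**
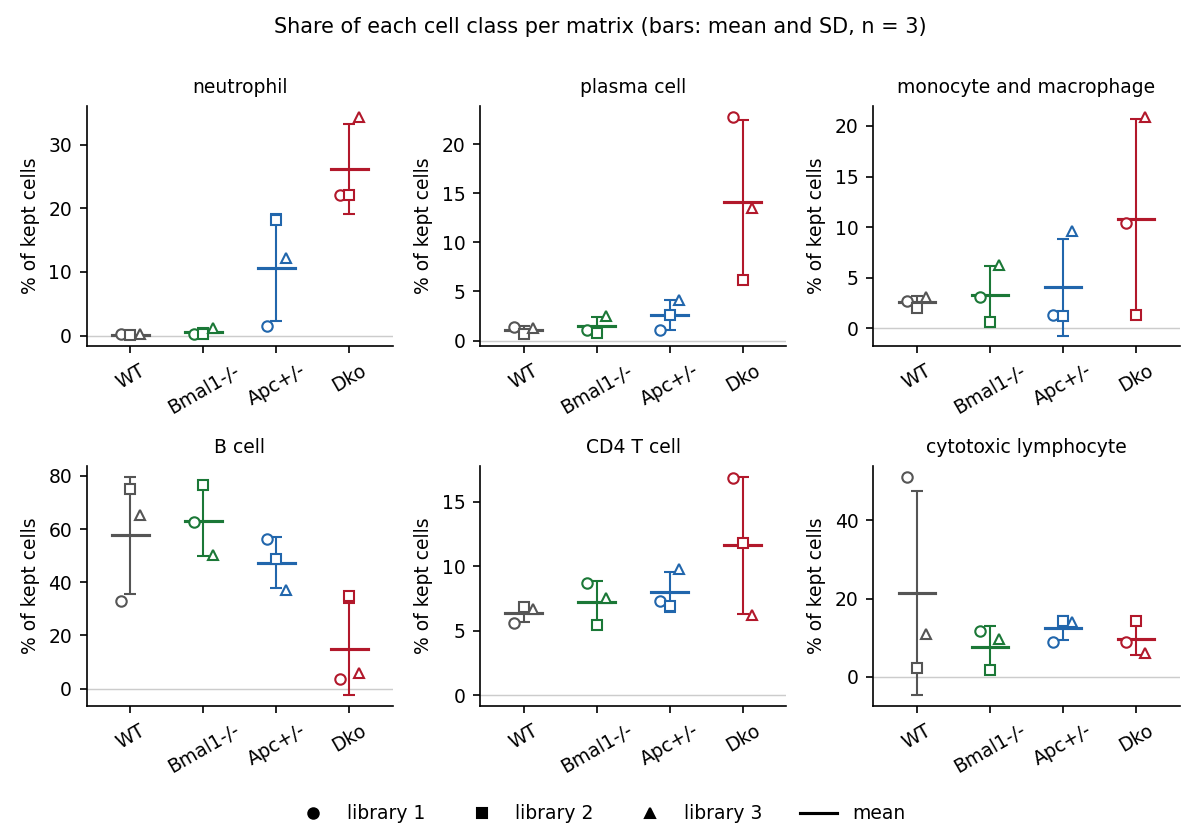
Share of each cell class among kept cells (percent, vertical axis) by genotype, with 1 point per library and the mean and SD of 3 libraries. Neutrophils lay between 22.1% and 34.4% in Dko, and at 0.175% on average in WT.

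The effect of Bmal1 loss on composition was compared next, without and with the Apc allele. Within libraries, Dko had 20.5, 3.91 and 22.2 points more neutrophils than Apc+/- (mean 15.5 ± 10.1), 21.7, 3.49 and 9.36 points more plasma cells (mean 11.5 ± 9.32), and a B cell share that differed by -52.5, -13.9 and -31.2 points (mean -32.5 ± 19.4). With 3 pairs the exact two-sided test cannot go below p = 0.25, the value of each. Over both Apc states the effect of Bmal1 loss was 7.98 points for neutrophils (exact permutation p = 0.269, adjusted p = 0.475, higher in 3 of 3 libraries), 5.94 for plasma cells and -13.6 for B cells, each with an adjusted p of 0.475. The permuted labels also carry the Apc differences, which were larger in these classes. These p-values therefore do not measure the spread of the Bmal1 effect alone and cannot show that it was absent. edgeR on cell counts called 3 classes in Dko against Apc+/-: germinal centre B cells (log2 fold change -3.74, adjusted p = 0.010), plasma cells (2.35, adjusted p = 0.0234) and B cells (-2.15, adjusted p = 0.0321). It called 0 classes in Bmal1-/- against WT.

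Bmal1-/- against WT asks what loss of the clock gene does where Apc is intact. B cells of Bmal1-/- mice had more Dusp1, a phosphatase that ends MAP kinase signalling (107 against 72.7 CPM, log2 fold change 0.54 ± 0.09, adjusted p = 0.004), and more Rhob, a small GTPase of early response (0.61 ± 0.12, adjusted p = 0.0454). Man2a2, a mannosidase of glycan processing, fell by 0.82 on the log2 scale (SE 0.15, adjusted p = 0.0105). Cytotoxic lymphocytes had more Atf3, a stress-induced transcription factor (25.4 against 1.98 CPM, 3.31 ± 0.50, adjusted p = 0.0408). Each held its direction in 3 of 3 libraries. Rhob did not pass without replicate 3 (adjusted p = 0.101) or without WT replicate 1 (0.264), Man2a2 not without replicate 2 (0.0797), and Atf3 not without replicate 1 (0.0797), replicate 2 (0.0541), replicate 3 (1.0) or WT replicate 1 (0.0703). Atf3 did not pass without the library block or with limma voom either. The genes of Bmal1-/- B cells that passed did so only with the libraries as a block, Dusp1 at an adjusted p of 0.571 and Man2a2 at 0.338 without it. Cytotoxic lymphocytes joined clusters 0, 4 and 7 in a mix that differed by matrix. Cluster 4 held 324, 1 and 20 cells in WT libraries 1, 2 and 3 and 7, 3 and 16 in Bmal1-/-. Atf3 was not fitted within these clusters, so its rise was not separated from the mix.

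The fixed list of dissociation and immediate early genes, to which Dusp1 and Atf3 belong, did not pass with an estimated correlation in either class. In B cells 1 of its 20 tested members rose over all genes tested and 4 adjusted over the list alone, with a median log2 fold change of 0.214 (camera adjusted p = 1.86e-05, adjusted p = 0.123 with an estimated correlation). In cytotoxic lymphocytes 1 of 20 rose, 2 adjusted over the list alone, median 0.359 (camera adjusted p = 2.65e-08, adjusted p = 0.0884 with an estimated correlation). Such genes also respond to tissue digestion. Over all cells, epithelial background genes had a median log2 fold change of 1.985 in Bmal1-/- against WT, with 0 of 19 members past the threshold over all genes and 5 adjusted over the list alone (camera adjusted p = 1.74e-21, adjusted p = 0.143 with an estimated correlation).

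In total, 6 gene and class pairs passed in the 3 planned classes for Bmal1-/- against WT: 5 of 10161 genes in B cells, 1 of 8891 in cytotoxic lymphocytes and 0 of 7724 in CD4 T cells (271 there at an unadjusted p under 0.05). The sum was 16 without replicate 1, 31 without replicate 2 and 15 without replicate 3. Over all cells edgeR called 0 of 13326 genes, with 252 at an unadjusted p under 0.05, DESeq2 12 and limma voom 0.

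Monocytes and macrophages, a class added after cell numbers had been seen, had less Il1b, the interleukin-1β gene, in Bmal1-/- than in WT (547 against 1260 CPM, log2 fold change -1.29 ± 0.19, adjusted p = 0.0086). Plac8, a gene of recently recruited monocytes, fell by 1.52 (SE 0.18, adjusted p = 0.00182), and the coagulation factor genes F5 and F10 by 3.09 and 1.97 (adjusted p = 0.0086 for both). Gzmb, the granzyme B gene of cytotoxic cells, rose by 6.12 ± 0.86 (adjusted p = 0.0086). All were in the same direction in 3 of 3 libraries. F5 and Gzmb lost no call in a leave-one-out run that tested them, but no gene of the class passed without replicate 3. Without the library block none of the 5 passed (adjusted p = 0.999 for Il1b, Plac8 and F5, 0.0787 for F10 and 0.684 for Gzmb). Gzmb did not pass with limma voom (0.128) or at resolution 2.0 (0.186) either. Other lymphocyte genes were counted in the same Bmal1-/- cells, Il17a with 80 counts against 1 in WT, Ifng with 45 against 4 and Foxp3 with 7 against 0. RNA or droplets shared with lymphocytes were not tested as the source of Gzmb. Il1b lost its call without replicate 2 (adjusted p = 0.0728) and without replicate 3 (0.282), Plac8 without replicate 3 (0.282) and F10 without replicate 1 (0.0545), replicate 2 (0.0796) and replicate 3 (0.282). The class joined clusters 13 and 14, and the Il1b-rich cluster 13 took 26.3% of it in WT and 7.43% (13 cells) in Bmal1-/-. Within cluster 14 alone, fitted after these values had been seen, Il1b was at -0.82 ± 0.72 (adjusted p = 0.999), F5 at -2.92 ± 0.70 (0.358) and F10 at -2.06 ± 0.51 (0.433). Plac8 was not lower there (0.999). The falls of Il1b and Plac8 were thus not shown within a cluster. The class gave 7 calls among 6934 genes, 0 without replicate 3 and 19 without WT replicate 1.

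Apc+/- against WT asks what the Apc allele does where the clock gene is intact. B cells of Apc+/- mice had more Traf1, an adaptor of TNF receptors (89.0 against 46.9 CPM, log2 fold change 0.94 ± 0.11, adjusted p = 9.25e-06), more Marcksl1, an actin-binding protein (0.80 ± 0.11, adjusted p = 1.7e-05), and more Dusp1 (0.66 ± 0.09, adjusted p = 1.7e-05). Tox, a chromatin factor of chronically stimulated lymphocytes, rose by 2.68 ± 0.46 from a low level (1.0 to 5.38 CPM, adjusted p = 0.000541), and Srp19, a signal recognition particle gene that neighbours Apc, by 0.58 ± 0.09 (adjusted p = 0.000168). These 5 genes were higher in 3 of 3 libraries and passed in every alternative run. Fosl2, an AP-1 family factor, rose by 1.07 ± 0.20 (adjusted p = 0.002), Grasp by 1.16 ± 0.17 (adjusted p = 6.85e-05) and Bhlhe40, a clock-controlled repressor, by 0.56 ± 0.12 (adjusted p = 0.00884; 0.201 without replicate 3). Slfn2, a regulator of lymphocyte quiescence, fell by 0.55 (SE 0.09, adjusted p = 0.000206; 0.0562 without replicate 3), and these 4 too held their direction in 3 of 3 libraries. None of the 4 passed without the library block (Fosl2 0.141, Grasp 0.92, Bhlhe40 0.848 and Slfn2 1.0), nor Fosl2 (0.145) and Bhlhe40 (0.181) with limma voom.

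The B cell class joined 5 clusters in a mix that differed by genotype and library. With libraries pooled, cluster 1 took 47.2% of it in WT, 34.5% in Bmal1-/-, 21.5% in Apc+/- and 19.6% in Dko, and cluster 8 took 17.3%, 24.5%, 33.2% and 41.8%. Cluster 1 held 73, 690 and 573 of 367, 1378 and 1083 B cells in WT libraries 1, 2 and 3. In Apc+/- it held 56, 202 and 146 of 538, 735 and 602, and in Dko 7, 90 and 24 of 27, 516 and 74. The order of the pooled shares thus did not hold in each library. Each cluster was fitted alone after these values had been seen. For Apc+/- against WT, the median of the genes called in the class was 0.29 to 0.47 within clusters, against 0.51 to 0.56 for the same genes in the class. Srp19 was at 0.54 to 0.75 within clusters, Dusp1 at 0.31 to 0.60 and Traf1 at 0.07 to 1.07, and only Srp19 in cluster 1 (adjusted p = 0.0481) and Slfn2 in cluster 8 (0.00606) passed among the genes above. How much of the class values went with the mix was not separated from the picking of these genes by them. For Bmal1-/- against WT, Dusp1 was at 0.10 to 0.66 and Rhob at 0.27 to 0.79 (lowest adjusted p = 0.23 and 0.736). Dko had too few B cells for such fits.

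Among the fixed lists in B cells, glycolysis and hypoxia genes had 1 of 15 members higher over all genes, Tpi1, and 6 adjusted over the list alone, with a median of 0.263 (camera adjusted p = 1.55e-07). Immune checkpoint genes had 1 of 11 higher, Tox, and 4 adjusted over the list alone (median 0.235, camera adjusted p = 0.000634). Neither list passed with an estimated correlation, where 0 of 370 list tests passed in the planned classes and all cells, against 121 with the preset value. B cells gave 53 genes higher and 19 lower of 10161 tested. CD4 T cells and cytotoxic lymphocytes gave 0 (329 and 333 at an unadjusted p under 0.05). The 72 calls became 251 without replicate 1 and 134 without WT replicate 1, and 39 without replicate 3.

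Over all cells, only Inhba (log2 fold change 7.50) rose and only Hddc3 (-1.53) fell by edgeR in Apc+/- against WT, with 1260 genes at an unadjusted p under 0.05 and 409 called by DESeq2. The count was 340 without replicate 1, 0 without replicate 2, 1 without replicate 3 and 1 without WT replicate 1. Neutrophil genes had the widest differences short of the threshold. S100a8, an abundant cytosolic protein of neutrophils, was at 4660 against 65.8 CPM (5.77 ± 0.97, adjusted p = 0.108), Retnlg at 617 against 8.27 (5.83 ± 0.90, adjusted p = 0.106) and Il1b at 2250 against 123 (3.96 ± 0.73, adjusted p = 0.115), each higher in 3 of 3 libraries. Of 17 members of the neutrophil list 0 passed over all genes and 16 adjusted over the list alone, median 5.05 (camera adjusted p = 1.94e-43, adjusted p = 0.0961 with an estimated correlation). These sums mix classes, and neutrophils went from 0.175% to 10.7% of cells.

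Monocytes and macrophages showed the strongest change of expression within a class. In Apc+/- against WT, Il1b rose from 1260 to 9680 CPM (log2 fold change 2.96 ± 0.20, adjusted p = 2.09e-07), Il1a, the other interleukin-1 gene, from 31.1 to 1210 (5.09 ± 0.33, adjusted p = 2.09e-07) and Inhba, which encodes the activin A subunit, from 1.52 to 1030 (8.85 ± 0.53, adjusted p = 2.09e-07). Cd14, the lipopolysaccharide co-receptor, rose by 2.32 ± 0.19 (adjusted p = 9.21e-07) and Sod2, a mitochondrial superoxide dismutase, by 2.88 ± 0.25 (adjusted p = 2.22e-06). Cd274, which encodes the checkpoint ligand PD-L1, rose from 13.1 to 119 CPM (2.94 ± 0.34, adjusted p = 3.05e-05). Arg2, an arginase of suppressive myeloid cells, rose by 5.65 ± 0.61 (adjusted p = 1.71e-05), Vegfa, the vascular growth factor, by 4.82 ± 0.50 (adjusted p = 6.51e-05), Slc2a1, a glucose transporter, by 3.30 ± 0.38 (adjusted p = 3.62e-05) and Spp1, osteopontin, by 6.13 ± 0.59 (adjusted p = 8.4e-05). Each was higher in 3 of 3 libraries and passed in every alternative run.

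Some genes of this class were picked after their values had been seen. Mrc1, the mannose receptor of resident macrophages, fell by 1.59 on the log2 scale (SE 0.23, adjusted p = 0.000291, lower in 3 of 3 libraries), and C1qa, a complement gene of the same cells, was at -1.65 ± 0.67 (adjusted p = 0.251). Ptgs2, the inducible cyclooxygenase, rose by 4.37 ± 0.43 (adjusted p = 0.000149), Nlrp3, the inflammasome sensor, by 2.15 ± 0.29 (adjusted p = 0.000127) and Arg1, the other arginase, by 5.94 ± 1.03 (adjusted p = 0.0202; 0.282 without replicate 2), each higher in 3 of 3 libraries. S100a8 was at 3.33 ± 1.55 (adjusted p = 0.32).

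Of the fixed lists in monocytes and macrophages of Apc+/- against WT, inflammatory cytokine and chemokine genes had 7 of 19 members higher over all genes and 8 adjusted over the list alone (median 2.151, adjusted p = 0.0108 with an estimated correlation). Suppressive myeloid genes had 8 higher and 1 lower of 16, 8 and 2 adjusted over the list alone (median 2.23, adjusted p = 0.0244 with an estimated correlation). Glycolysis and hypoxia genes had 12 of 15 higher by either count (median 1.479, adjusted p = 0.0311 with an estimated correlation), and immune checkpoint genes 3 of 10, 4 adjusted over the list alone (median 0.815, adjusted p = 0.0311 with an estimated correlation). The neutrophil list had 8 of 15 higher, 9 adjusted over the list alone (median 3.362, adjusted p = 0.0912 with an estimated correlation). In all, 322 genes rose and 135 fell of 6934 tested, with 222 calls without replicate 2, 148 without replicate 3 and 318 without the library block. Mitochondrial genes, which also track cell quality, were 4 of those lower in this class, and 4 in Dko against WT. Over all cells the median mitochondrial share per matrix was 3.35% to 3.59% in WT, 2.88% to 3.32% in Apc+/- and 1.76% to 2.44% in Dko.

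The class had 118 cells in WT (30, 36 and 52 per library), 175 in Bmal1-/-, 188 in Apc+/- (13, 19 and 156) and 356 in Dko (75, 19 and 262). It joined cluster 13, led by Lyz2, Thbs1, Cxcl2, Il1b, Cd14 and Arg1, and cluster 14, led by Retnla, C1qa, Fn1 and Mrc1. Cluster 13 took 26.3% of the class in WT, 7.43% in Bmal1-/-, 62.2% in Apc+/- and 66.3% in Dko. Within cluster 13 alone, Apc+/- against WT gave 2.19 ± 0.26 for Il1b (adjusted p = 0.000314), 8.93 ± 0.67 for Inhba (adjusted p = 2.87e-05) and 2.82 ± 0.62 for Cd274 (adjusted p = 0.0149). Arg1 was at 5.37 ± 1.26 there (adjusted p = 0.0572) and Mrc1 at 0.10 ± 0.81 (adjusted p = 0.979).

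**Figure D2:**
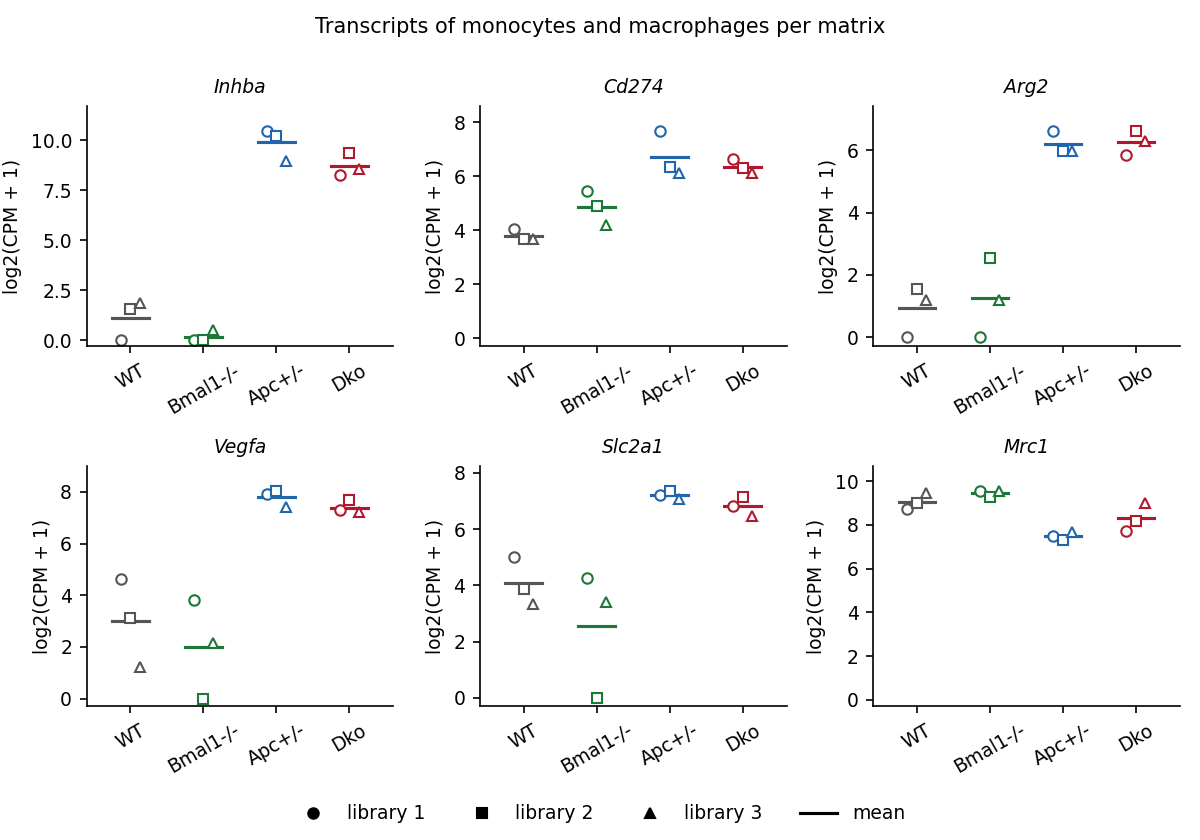
Expression of selected genes in monocytes and macrophages (log2 of normalised CPM plus 1, vertical axis) by genotype, with 1 point per library and a line at the mean of 3 libraries. Inhba, Cd274, Arg2, Vegfa and Slc2a1 lay higher in each Apc+/- and Dko library than in each WT library, and Mrc1 lay lower in each Apc+/- library.

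Dko against Apc+/- asks what loss of the clock gene adds once the Apc allele is present. B cells of Dko had more Dusp1 than those of Apc+/- (191 against 116 CPM, log2 fold change 0.69 ± 0.11, adjusted p = 0.000309), more Fgl2, a secreted fibrinogen-like regulator of immunity (1.30 ± 0.22, adjusted p = 0.00145; 0.052 without replicate 3), and more Bhlhe41, a transcriptional repressor of the clock found in innate-like B cells (1.25 ± 0.25, adjusted p = 0.0105; 0.554 without replicate 2). Nhp2, a component of small nucleolar ribonucleoproteins, fell by 0.73 (SE 0.15, adjusted p = 0.0202; 0.143 without replicate 2 and 0.126 without replicate 3). All held their direction in 3 of 3 libraries. Nt5e, the ectoenzyme CD73, was at 1.34 ± 0.27 (adjusted p = 0.0105), higher in 2 of 3 libraries, with 0.957 without replicate 2. None of the 7 named values of B cells in this contrast passed in every alternative. Without the library block Dusp1 was at 0.11, Fgl2 at 1.0, Bhlhe41 at 0.705 and Nhp2 at 0.377, and with limma voom they were at 0.06, 0.11, 0.109 and 0.284. Replicate 2 held 516 of the Dko B cells, against 27 and 74 in the others. B cells gave 13 calls of 10161 genes, and CD4 T cells and cytotoxic lymphocytes 0 (551 and 241 at an unadjusted p under 0.05). The sum was 56 without replicate 1, 32 without replicate 2, 30 without replicate 3 and 26 without WT replicate 1.

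The main fit did not call the myeloid programme seen in Apc+/- different in Dko, which does not show it to be the same. In monocytes and macrophages Inhba had 301, 658 and 380 CPM in Dko libraries 1, 2 and 3 against 1400, 1190 and 503 in Apc+/-. Arg2, at 57.1, 98.0 and 77.5 against 97.5, 62.3 and 62.2, went both ways. In monocytes and macrophages of Dko against Apc+/-, Il1b was at -0.21 ± 0.18, Cd274 at -0.36 ± 0.25 and Inhba at -1.15 ± 0.30 (adjusted p = 0.484), and edgeR called 0 of 6934 genes, with 306 at an unadjusted p under 0.05, DESeq2 10 and limma voom 0. Short of the threshold, Pde2a, a phosphodiesterase gene on chromosome 7, was at 1.90 ± 0.34 (adjusted p = 0.225), Mgl2, a macrophage lectin, at 1.65 ± 0.33 (adjusted p = 0.285) and Tmem176a, an ion channel gene of antigen-presenting cells, at 1.23 ± 0.24 (adjusted p = 0.243). In neutrophils (15 cells in Apc+/- library 1 and 160 to 431 in the other matrices compared), S100a8 was at 0.72 ± 0.28 (adjusted p = 0.953) and Cd274 at -0.25 ± 0.25 (adjusted p = 0.999). Trim30d and Trim12a, antiviral factor genes on chromosome 7, fell by 6.61 (SE 0.38) and 5.53 (SE 0.32) there (adjusted p = 4.08e-26 for both, lower in 3 of 3 libraries). Prok2, a chemoattractant of bone marrow neutrophils, rose by 1.63 ± 0.31 (adjusted p = 0.00186; 1.0 without replicate 2). The B cell genes Cd79a and Ebf1 fell by 1.41 and 1.63 (adjusted p = 0.00015 for both; Cd79a 0.0539 without replicate 2 and 0.283 without replicate 3). Prok2, Cd79a and Ebf1 did not pass with limma voom (adjusted p = 1.0 for each) or without the library block (0.404, 0.145 and 1.0), nor Prok2 and Ebf1 with DESeq2 (0.541 and 0.0551). Neutrophils gave 11 calls, 41 without replicate 1 and 19 without replicate 3.

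Plasma cells of Dko against Apc+/- gave 44 calls. Bcl11a, a transcription factor of B cells, fell by 2.93 (SE 0.42, adjusted p = 0.00675), Cd86, a costimulatory ligand, by 2.93 (SE 0.51, adjusted p = 0.0204), Cxcr4, a homing receptor, by 2.21 (SE 0.36, adjusted p = 0.0204) and Ciita, the master regulator of MHC class II, by 3.17 (SE 0.61, adjusted p = 0.0438). Bst2, an interferon-induced restriction factor, rose by 1.37 ± 0.26 (adjusted p = 0.0309). All held their direction in 3 of 3 libraries. With high doublet scores left out, Cd86, Cxcr4 and Bst2 (adjusted p = 0.0732 for each) and Ciita (0.17) lost their calls. B cell markers had 3160, 1950 and 2790 unscaled CPM in plasma cells of Apc+/- libraries 1, 2 and 3 and 1370, 1630 and 1110 in those of Dko, where B cells were fewer, so that B cell RNA counted in plasma cells is not excluded. The MHC class II list had 1 of 11 members lower over all genes and 9 adjusted over the list alone, median -1.624, and the plasma cell secretory list 0 of 14 and 5 higher adjusted over the list alone, median 0.513. The scaling added 0.61 to each log2 fold change of this contrast, more than the latter median, so that a rise of the secretory list was not separated from scaling. The 44 calls became 20 without replicate 1, 164 without replicate 2 and 2 without replicate 3, where Bcl11a was at an adjusted p of 0.254, Cd86 at 0.857, Cxcr4 and Ciita at 0.855 and Bst2 at 0.703. Without replicate 1 Cd86 was at 0.0954, Ciita at 0.0689 and Bst2 at 0.171, and Ciita was at 0.0809 without WT replicate 1.

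Over all cells edgeR called only Hddc3 in Dko against Apc+/- (2.36 ± 0.15, adjusted p = 0.00205, higher in 3 of 3 libraries; 0.245 without replicate 1, 0.0554 without replicate 2 and 0.254 without replicate 3), with 4055 genes at an unadjusted p under 0.05 and 1980 called by DESeq2. Mzb1, a chaperone of antibody secretion, was at 1870 against 561 CPM (1.71 ± 0.29, adjusted p = 0.0709), Cd274 at 85.5 against 41.5 (1.00 ± 0.26, adjusted p = 0.0726) and Foxp3, the regulatory T cell factor, at 11.8 against 3.02 (1.89 ± 0.65, adjusted p = 0.112), each higher in 3 of 3 libraries. The scaling added 0.51 to each, and the sums mix classes. Unscaled Cd274 CPM were 85.4, 54.0 and 49.1 in Dko against 42.4, 44.7 and 46.0 in Apc+/-. Within monocytes and macrophages Cd274 was at -0.36. Its unscaled means in Dko and Apc+/- were 33.8 and 36.4 in B cells, 24.0 and 26.1 in CD4 T cells, and 26.3 and 23.9 in cytotoxic lymphocytes. The rise over all cells was thus not separated from scaling and composition. All 14 plasma cell secretory genes were higher adjusted over the list alone and 0 over all genes, median 2.019 (camera adjusted p = 1.32e-16, adjusted p = 0.519 with an estimated correlation).

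Dko against WT joins both alleles. Over all cells S100a8 rose from 65.8 to 14400 CPM (log2 fold change 7.99 ± 1.06, adjusted p = 0.00571), Il1b from 123 to 5470 (5.43 ± 0.76, adjusted p = 0.00582), Arg2 by 6.84 ± 0.80 (adjusted p = 0.00565) and Cd274 from 23.9 to 85.5 (1.82 ± 0.26, adjusted p = 0.00582), each higher in 3 of 3 libraries. Tnf rose by 2.03 ± 0.41 (adjusted p = 0.0132) and Arg1 by 3.76 ± 0.69 (adjusted p = 0.0105). Pdcd1, which encodes PD-1, was at -0.04 ± 0.33, Ifng at 0.44 ± 1.08, Gzmb at -0.40 ± 1.67, Il17a at 0.09 ± 1.56 and Foxp3 at 1.85 ± 0.65 (adjusted p = 0.0686). WT library 1 weighed on these, with 138 CPM of Il17a against 4.15 and 0.484 in the other WT libraries and 1070 of Gzmb against 8.82 and 139. Over all alternatives Il17a ran from -0.90 to 3.92 (lowest adjusted p = 0.036), Gzmb from -1.77 to 2.25 and Ifng from -0.29 to 1.94. In all, 1951 genes rose and 1508 fell of 13326. The count was 0 without replicate 3 (S100a8, Il1b, Arg2 and Cd274 at an adjusted p of 0.224) and 15 once neutrophil and plasma clusters were left out of the sums. There Cd274 was at 0.89 (adjusted p = 0.0836), S100a8 at 4.89 (0.0743), Il1b at 4.05 (0.0664) and Arg2 at 4.78 (0.0746).

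The fixed lists were tested in the Dko to WT contrast over all cells, where composition was not removed and the scaling added 0.57 to each log2 fold change. Of 17 neutrophil genes 15 rose over all genes and 16 rose and 1 fell adjusted over the list alone (median 6.966, adjusted p = 0.262 with an estimated correlation), and of 14 plasma cell secretory genes 14 rose by either count (median 2.668, adjusted p = 0.262 with an estimated correlation). Inflammatory genes had 11 of 20 higher (14 adjusted over the list alone, median 2.236), suppressive myeloid genes 9 of 18 (11 adjusted over the list alone, median 2.271) and glycolysis and hypoxia genes 12 of 15 (12 adjusted over the list alone, median 0.987), each with an adjusted p of 0.276 with an estimated correlation. Dissociation and immediate early genes had 13 higher and 1 lower of 20 (16 and 1 adjusted over the list alone, median 1.181, adjusted p = 0.262 with an estimated correlation), interferon response genes 10 of 19 higher (10 adjusted over the list alone, median 0.834, adjusted p = 0.352 with an estimated correlation) and glucocorticoid response genes 4 of 10 (4 adjusted over the list alone, median 0.631, 0.352). MHC class II genes had 7 of 11 lower (10 adjusted over the list alone, median -0.741, adjusted p = 0.352 with an estimated correlation) and T cell naive and memory genes 4 of 9 lower (6 lower and 1 higher adjusted over the list alone, median -1.292, 0.604). Epithelial background genes had 3 of 19 higher (8 adjusted over the list alone, median 2.92, adjusted p = 0.38 with an estimated correlation) and proliferation genes 1 of 14 lower (0 adjusted over the list alone, median -0.597, adjusted p = 0.604 with an estimated correlation).

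The remaining lists did not pass camera with the preset correlation in that contrast. Core clock and output genes had 4 of 17 higher and 1 lower (4 and 2 adjusted over the list alone, median 0.18, adjusted p = 0.233). Immune checkpoint genes had 4 of 16 higher and 2 lower by either count, adjusted over the list alone included, and their median of -0.056 was opposite in sign to the mean of 0.532 and to the test (adjusted p = 0.233). Regulatory T genes had 1 of 12 higher by either count, adjusted over the list alone included (median 0.789, adjusted p = 0.136), type 3 cytokine genes 2 of 13 higher (2 adjusted over the list alone, median 0.092, 0.787), cytotoxic effector genes 1 higher and 1 lower of 16 (the same adjusted over the list alone, median -0.24, 0.825), oxidative phosphorylation genes 2 of 16 lower (2 adjusted over the list alone, median -0.186, 0.233) and T cell tissue residence genes 0 of 9 (0 adjusted over the list alone, median 0.19, 0.607). The red cell background list had too few members past the count filter to be tested in any class. Its Hbb-bt had 38, 121, 183 and 12 counts in WT, Bmal1-/-, Apc+/- and Dko.

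Within classes, B cells of Dko had more Dusp1 than those of WT (log2 fold change 1.36 ± 0.11, adjusted p = 5.83e-12), which passed in every alternative run. Fgl2 rose by 2.19 ± 0.23 (adjusted p = 6.76e-08), Rhob by 1.17 ± 0.15 (adjusted p = 0.000118) and Ctla4, an inhibitory receptor, by 1.56 ± 0.31 (adjusted p = 0.00242; 0.638 without replicate 2), while Slfn2 fell by 0.84 (SE 0.12, adjusted p = 2.76e-05). In library 1 the Ctla4 value rested on 27 Dko B cells (7.53 against 5.8 CPM in WT). Ctla4 is also a gene of T cells. CD4 T cells numbered 375 beside 617 B cells in Dko, against 298 beside 2828 in WT. RNA or droplets shared with T cells were not tested as its source. CD4 T cells had more Ly6a, an interferon-induced surface protein (471 against 162 CPM, 1.55 ± 0.16, adjusted p = 6.79e-05), Reep5 (1.21 ± 0.15, adjusted p = 0.000496; 0.0878 without replicate 3) and the immediate early gene Ier2 (1.13 ± 0.17, adjusted p = 0.00533; 0.163 without replicate 1 and 0.09 without replicate 3). All were in the same direction in 3 of 3 libraries. Ly6a lost its call at resolution 0.5 (adjusted p = 0.14) and without the library block (0.396). None of these 3 CD4 T cell genes passed in every alternative run. CD4 T cells joined clusters 5 and 6, and cluster 6 took 28.5% of them in WT and 65.3% in Dko. Within cluster 6 alone, fitted after these values had been seen, Ly6a was at 1.07 ± 0.19 (adjusted p = 0.0141) and Reep5 at 0.68 ± 0.19 (0.368), and within cluster 5 at 0.65 ± 0.56 (0.999) and 1.13 ± 0.24 (0.0365). B cells gave 60 genes higher and 16 lower, CD4 T cells 9 and 1, and cytotoxic lymphocytes 0 (423 at an unadjusted p under 0.05). The 86 calls became 256 without replicate 1 and 150 without WT replicate 1, and B cell calls other than Dusp1 among the named genes did not pass without the library block (Fgl2 at 0.216, Slfn2 at 0.792).

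In monocytes and macrophages, Dko against WT gave 2.75 ± 0.19 for Il1b (adjusted p = 6.37e-07), 7.70 ± 0.53 for Inhba (adjusted p = 1.5e-06), 5.76 ± 0.59 for Arg2 (adjusted p = 1.22e-05), 2.58 ± 0.33 for Cd274 (adjusted p = 0.000163) and 2.51 ± 0.25 for Cxcl16, a chemokine that draws CXCR6-bearing T cells (adjusted p = 1.22e-05), each higher in 3 of 3 libraries. A total of 356 genes rose and 168 fell, with 190 calls without replicate 2, 123 without replicate 3 and 334 without the library block. Inflammatory and suppressive myeloid lists both had an adjusted p of 0.0269 with an estimated correlation, on 6 of 19 members higher (10 adjusted over the list alone) and on 7 higher and 1 lower of 16 (11 and 1 adjusted over the list alone). Neutrophil list genes had 2350, 11700 and 3920 unscaled CPM in this class in Dko libraries 1, 2 and 3 against 503, 581 and 481 in WT, and the share of neutrophil RNA was not estimated for this contrast. Plasma cells of Dko against WT gave 22 genes higher and 58 lower, among them Cxcr4 (-2.67 ± 0.38, adjusted p = 0.0114), Hhex (-5.10 ± 0.84, adjusted p = 0.0122) and Edem1, a factor of endoplasmic reticulum quality control (1.13 ± 0.23, adjusted p = 0.0282), each in the same direction in 3 of 3 libraries. That count was 31 without replicate 1, 276 without replicate 2, 0 without replicate 3 and 11 without WT replicate 1. The scaling added 0.43 to each log2 fold change of Dko against WT in plasma cells. B cell markers in plasma cells had 2090, 2990 and 3300 unscaled CPM in WT against 1370, 1630 and 1110 in Dko, so that B cell RNA is not excluded here either. With sex as a term the count was 1, with Cxcr4 and Hhex at an adjusted p of 0.071 and Edem1 at 0.148. Hhex also lost its call without replicate 1 (0.0644) and without WT replicate 1 (0.0502), Cxcr4 without replicate 3 (0.515), and Edem1 without replicate 3 (0.746) and without WT replicate 1 (0.0652).

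The interaction asks whether the effect of Bmal1 loss depended on the Apc allele. edgeR called 0 genes over all cells (1921 at an unadjusted p under 0.05, DESeq2 47) and 0 in B cells, CD4 T cells, cytotoxic lymphocytes (564, 294 and 327) and monocytes and macrophages (369, DESeq2 17, limma voom 1). In B cells Ltb, which encodes lymphotoxin β, was at 0.58 ± 0.13 (adjusted p = 0.17), and over all cells Bst2 was at 1.96 ± 0.47 (adjusted p = 0.329), in the same direction in 3 of 3 libraries. Planted 4-fold interactions were found in 47% of cases over all cells, 73% in B cells, 56% in CD4 T cells, 52% in cytotoxic lymphocytes and 49% in monocytes and macrophages, so that smaller ones were largely out of reach.

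Genes near the targeted alleles differed by genotype in several classes. Trim12a (chromosome 7, 104299894 to 104315466), which lies near Arntl, had 86.6, 73.6 and 66.5 CPM over all cells of Apc+/- libraries 1, 2 and 3 and 1.27, 1.74 and 0.945 in Dko. It had 48.1, 2.56 and 99.7 in WT and 1.97, 44.1 and 1.36 in Bmal1-/-, so that library 2 ran opposite to the others, and so did its neighbours Trim5 and Trim30d. Trim12c, which lies between Trim12a and Trim30d, overlapped between all genotypes. It had 55.9, 42.8 and 56.8 in WT, 46.9, 44.0 and 41.5 in Bmal1-/-, 41.4, 50.5 and 48.7 in Apc+/- and 33.3, 54.8 and 43.7 in Dko. These genes are close paralogs, so the share of each is uncertain. Hddc3 (chromosome 7, 80343104 to 80350547), a nucleotide hydrolase, had 2.55, 2.25 and 2.72 in Apc+/- against 9.3, 8.97 and 8.9 in Dko. It had 8.57, 6.97 and 7.28 in WT and 11.6, 10.2 and 11.6 in Bmal1-/-, so that Apc+/- stood apart. On chromosome 18, Srp19 had 139, 114 and 125 in Apc+/- and 138, 111 and 127 in Dko, against 88.3, 74.2 and 90.2 in WT.

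**Figure D3:**
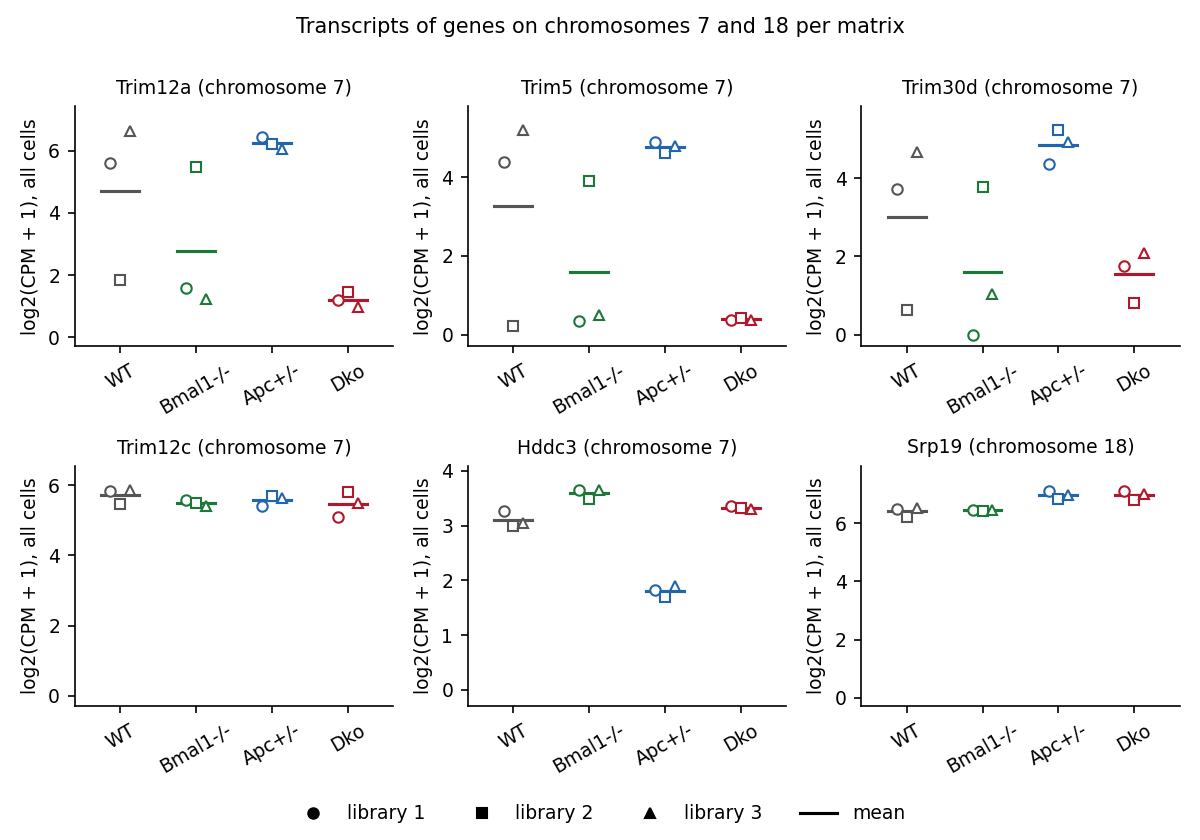
Expression of genes near Arntl and Apc over all cells (log2 of CPM plus 1, vertical axis) by genotype, with 1 point per library and a line at the mean of 3 libraries. Trim12a was at 2.56 in 1 WT library and at 44.1 in 1 Bmal1-/- library, and Srp19 lay higher in each Apc+/- and Dko library than in WT.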

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

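The tests on the targeted loci, on free RNA behind B cell markers, on the amount of neutrophil RNA taken up, on sex, and on other splits of the matrices were chosen only after the results they bear on had been seen.

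Some calls lay near the targeted genes. Of 64 genes called in Dko against Apc+/- in any class, 8 lay within 35 Mb of Arntl (12.5%, against 3.75% of tested genes), among them Hddc3, Trim5, Trim12a and Trim30d. Of 513 called in Apc+/- against WT, 8 lay within 5 Mb of Apc (1.56% against 0.642%), among them Apc itself, Srp19, Reep5 and Cd14. Several of these had prompted the count, and the Trim genes are paralogs. Without the genes looked at before, 3 of 59 calls lay near Arntl (5.08%, one-sided Fisher exact p = 0.371) and 4 of 509 near Apc (0.786%, one-sided Fisher exact p = 0.373), so that a wider gathering was not shown. In Dko against WT 29 of 669 calls lay near Arntl (4.33%) and 7 near Apc, and in Bmal1-/- against WT 2 of 13 lay near Arntl. Loss of Bmal1 in the cells themselves as the reason for low Trim12a would be argued against by 2.56 CPM in WT library 2, where the highest Bmal1-/- library had 44.1. This holds only if the labels do. That the WT and Bmal1-/- labels of library 2 were exchanged stays open, and so does that loss: of 9 such genes on chromosome 7, the 3 Trim genes part all WT from all Bmal1-/- matrices only after that exchange, while 4 (Gm26862, Gm35082, Hddc3 and Man2a2) do so only as labelled, and chance alone would part 10% of genes with 3 against 3. Variants of another strain carried along with each allele are a candidate explanation that stays open, and an effect of the alleles themselves on their neighbours was not tested. Variants carried with the Bmal1 allele would not by themselves give the lower Hddc3 of Apc+/- against WT. By name neither of these genotypes carries that allele.

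Monocytes and macrophages gave 457 calls in Apc+/- against WT although their clusters were mixed differently and neutrophils were many. A shift in the mix is argued against as the whole cause for 332 of these genes as a set, those testable within cluster 13 alone. Their median signed log2 fold change there was 1.48, which is 99.1% of their median in the whole class (1.63 for all 457). Of the 332, 324 kept their direction. Called genes that could not be tested within cluster 13 are not covered, and a shift in the mix stays open for them. It also stays open for the lower values of the resident macrophage genes Mrc1 and C1qa in the class. Within cluster 13 Mrc1 was at 0.10 ± 0.81, and C1qa, which was not called in the class, at 1.26 ± 0.82. Neutrophil RNA, at the share that S100a8 and S100a9 allow (-0.1% to 2.44% of counts), would give a median of 1.17% of the rise of 322 genes called higher, and over 50% for 1 of them. A change of state within these cells, or the arrival of others that cluster with them, may underlie the difference, and neither was tested further. Sex, which differed between WT and Apc+/- in library 3 alone, is argued against as the whole cause. With sex as a term the median signed log2 fold change of the called genes was 104% of that without it, and it was 106% without library 3, though calls fell to 288 of the same genes and to 148 in all.

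Transcripts of 1 class were counted in another. The neutrophil list's share of counts in B cells of Dko was 0.737 to 1.15 times that in WT of the same library, and 0.915 to 1.59 times without Cxcr4, which B cells express, so that free RNA shared within a pool is a candidate source, and droplets with a neutrophil and a B cell are argued against by 0.0% of these counts (0 of 617 cells) lying in cells with at least 20 of them. Neutrophil RNA taken up before pooling is argued against as the whole source by the same ratio of at most 1.59, since neutrophils were 0.175% of cells in WT and 26.2% in Dko. A test of it planned before, in which 40.0% of 10 genes kept the proportion they have in neutrophils, decided nothing by itself. B cell markers in cytotoxic lymphocytes were 20.3, 1.31 and 1.7 times as high in Apc+/- as in Dko of libraries 1, 2 and 3. For these 2 genotypes this leaves shared free RNA open in libraries 2 and 3. Over all 4 genotypes the markers' share differed by at least 6.71-fold within each library, which argues against shared free RNA as the whole source. In Apc+/-, 53.1% to 95.5% of these counts lay in few cells (26 of 530), as droplets with a pair of cells would give. The falls of Cd79a and Ebf1 in Dko neutrophils could have either source, and this was not tested.

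With 3 matrices against 3 there are 10 splits, too few for a share under 0.05, so the real count and the highest of the other splits are given. For Bmal1-/- against WT, 10 of 10 splits gave at least as many calls over all cells (real 0, highest other 4), 6 in the planned classes (real 6, highest other 18, from the split that exchanges WT and Bmal1-/- in library 2) and 2 in monocytes and macrophages (real 7, highest other 7). For Apc+/- against WT it was 2 over all cells (real 2, highest other 13) and 2 in the planned classes (real 72, highest other 246), the latter with WT of library 1 set beside Apc+/- of libraries 2 and 3, which points to a structure of the samples, and 1 in monocytes and macrophages (real 457, highest other 1). For Dko against Apc+/- it was 3 over all cells (real 1, highest other 1), 2 in the planned classes (real 13, highest other 25), 10 in monocytes and macrophages (real 0, highest other 2), 1 in plasma cells (real 44, highest other 5) and 5 in neutrophils (real 11, highest other 95, with Apc+/- of libraries 1 and 3 set beside Dko of library 3). For Dko against WT it was 1 over all cells (real 3459, highest other 0), 1 in the planned classes (real 86, highest other 48), 1 in monocytes and macrophages (real 524, highest other 9) and 1 in plasma cells (real 80, highest other 12). For the interaction, 31 of 31 splits gave at least as many calls as the real 0, with up to 4153 over all cells and 445 in the planned classes, so chance is not excluded. A real count of 0 fixes that outcome, and a split that mixes genotypes carries their differences into the interaction, so these counts decide nothing further.

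Some genes moved 1 way with Bmal1 loss in each library where Apc was intact and the other way in each library where it was not. The difference was tested by the interaction term, and none passed. In cytotoxic lymphocytes it was -4.51 for Atf3, 1.06 for Vsir, -1.3 for Jun and -0.95 for Fosb (log2). In B cells it was -0.63 for Lncpint, 0.58 for Ltb, -0.41 for Marcksl1 and -0.7 for Kcnq1ot1, and in CD4 T cells -0.93 for Cxcr4. In monocytes and macrophages it was 3.92 for Hp (adjusted p = 0.073), 3.55 for F5 (adjusted p = 0.0816), -0.98 for Sgk1, -1.67 for Lmnb1, -1.34 for Cd274 and -2.46 for Tnf. In plasma cells it was -3.32 for Gadd45a, 1.8 for Bst2 and -3.0 for Bach2. The adjusted p of the others ran from 0.127 to 1.0, and 18 such values were found among 194 checked, for which no chance number is given since many were picked for 1 direction in all libraries. Groups of 3 were not tested for a library that stands apart. Oligo counts outside the comparisons included other oligos than a matrix's own, up to 4.82% of oligo counts in Apc+/- library 1.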

How the results depend on the processing

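The sex term, leaving out WT replicate 1, the share denominator without neutrophils, sums without neutrophil and plasma clusters, classes with at least 10 cells and the neutrophil comparison were chosen after seeing the data, and the other alternatives before. Of 356 values of named genes, 169 passed, 56 of these passed in every alternative run for them, and 0 turned direction among those past the threshold. A change of sign between values that both missed the threshold was not counted as a turn. Among monocyte and macrophage genes 26 of 29 values of Apc+/- against WT and 22 of 25 of Dko against WT passed in every alternative, among B cell genes 5 of 18 and 1 of 17, and over all cells 0 of 11 of Dko against WT. DESeq2 size factors in place of TMM moved the median of all genes by at most 0.03, while TMM itself moved all genes of Dko against WT over all cells by 0.57 against unscaled counts. All counts rest on 3 matrices per genotype and, in small classes, on few cells. The cause was not tested except where a setting tests fewer or more genes or classes.

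The library was a block in each fit. With no replicate block the planned classes gave 0 calls for Bmal1-/- against WT (6 with it), 6 for Apc+/- against WT (72), 0 for Dko against Apc+/- (13) and 3 for Dko against WT (86), monocytes and macrophages 1 for Bmal1-/- against WT (7) and 334 for Dko against WT (524), and neutrophils 3 (11). For the share of cells it gave 1 class with an Apc effect (0 with it), neutrophils, at the same 18.053 points.

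DESeq2 called 12 genes over all cells for Bmal1-/- against WT (0 by edgeR), 409 for Apc+/- against WT (2), 1980 for Dko against Apc+/- (1) and 47 for the interaction (0). In the planned classes it called 39 for Apc+/- against WT and 1 for the interaction, in monocytes and macrophages 16 for Bmal1-/- against WT and 10 for Dko against Apc+/-, in plasma cells 104 for Dko against Apc+/- (44) and 182 for Dko against WT (80), and in neutrophils 5. limma voom called 0 over all cells for Apc+/- against WT, in the planned classes 0, 11 and 3 for Bmal1-/- against WT, Apc+/- against WT and Dko against Apc+/-, in plasma cells 212 for Dko against WT and in neutrophils 3.

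With no low-count filter, which tests more genes, the planned classes gave 137, 231, 299 and 610 calls for Bmal1-/- against WT, Apc+/- against WT, Dko against Apc+/- and Dko against WT, and 140 for the interaction. Monocytes and macrophages gave 135, 743, 227 and 879 for the same 4 contrasts, plasma cells 301 and 409 for the latter 2, and Apc+/- against WT over all cells 4. With only the 2 genotypes compared, which uses fewer matrices, the planned classes gave 47 for Bmal1-/- against WT, 72 for Dko against Apc+/- and 178 for Dko against WT, all cells 0 for Apc+/- against WT, 3 for Dko against Apc+/- and 1829 for Dko against WT, monocytes and macrophages 3 for Bmal1-/- against WT and 2 for Dko against Apc+/-, and plasma cells 176 for Dko against WT.

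With sex as a term, the planned classes gave 15 for Bmal1-/- against WT and 34 for Apc+/- against WT, all cells 0 for Apc+/- against WT and 1046 for Dko against WT, monocytes and macrophages 332 and plasma cells 1 for Dko against WT. With an absolute log2 fold change of at least 1 required, the planned classes gave 2, 14 and 46 for Bmal1-/-, Apc+/- and Dko against WT, and all cells 1579 for Dko against WT. With at least 50 cells, which leaves fewer classes, the planned classes gave 0, 0, 0 and 10 in the 4 pairwise contrasts, and with at least 10 cells, which adds classes, 13, 529, 57 and 690.

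For Apc+/- against WT over all cells, DESeq2 size factors gave 4 calls, leaving out immunoglobulin genes 7 and leaving out cells with high doublet scores 4. Leaving out those cells gave 2 for Dko against Apc+/- over all cells, 6 for it and 35 for Dko against WT in plasma cells, and 2 classes with an Apc effect, neutrophils at 18.382 points. Leaving out neutrophil and plasma clusters gave 2 for Dko against Apc+/- and 15 for Dko against WT. Resolution 0.5 gave 21 calls for Dko against Apc+/- in the planned classes. A denominator without plasma, B and non-immune cells gave 4 classes with an Apc effect, neutrophils at 28.614 points. edgeR on cell counts gave 6, with log2 values of -1.345 for B cells and 5.692 for neutrophils. Camera with an estimated correlation called 0 of 370 list tests (121 preset), and 8 of 90 in monocytes and macrophages (27 preset).

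Leave-one-out, over each of the 3 libraries and WT replicate 1, gave for Bmal1-/- against WT 7 to 31 calls in the planned classes and 0 to 19 in monocytes and macrophages. For Apc+/- against WT it gave 0 (without replicate 2) to 340 (without replicate 1) over all cells, 39 (without replicate 3) to 251 (without replicate 1) in the planned classes and 148 (without replicate 3) to 506 in monocytes and macrophages. For Dko against Apc+/- it gave 0 to 1 over all cells, 26 to 56 in the planned classes, 0 to 3 in monocytes and macrophages, 2 (without replicate 3) to 164 (without replicate 2) in plasma cells and 11 to 41 in neutrophils. For Dko against WT it gave 0 (without replicate 3) to 2994 over all cells, 85 to 256 in the planned classes, 123 to 558 in monocytes and macrophages and 0 (without replicate 3) to 276 (without replicate 2) in plasma cells. For the interaction it gave 0 to 1 over all cells and 0 to 4 in the planned classes. Without 1 library each genotype kept 2 matrices.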

Other observations

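The levels of Igha in B cells and of Foxp3 in CD4 T cells were picked after their values had been seen, while the lists and the tests of shares were fixed before.

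Minor classes also differed between genotypes. Group 2 innate lymphoid cells, a source of type 2 cytokines, made up 0.767% of cells in WT and 3.56% ± 3.12 in Dko, dendritic cells 0.936% and 2.88% ± 1.40, and mast cells and basophils 0.068% and 0.831%. Over both Bmal1 states the Apc allele went with 1.64 points more group 2 innate lymphoid cells (exact permutation p = 0.0370, adjusted p = 0.0617), 1.41 points more dendritic cells (p = 0.0185, adjusted p = 0.0556) and 0.633 points more mast cells and basophils (p = 0.0278, adjusted p = 0.0556), each in 3 of 3 libraries, and none passed the adjusted threshold. In library 1, Apc+/- minus WT alone was -0.511 points for both group 2 innate lymphoid cells and dendritic cells. Germinal centre B cells, where B cells mutate their receptors, made up 1.41% in WT, 2.24% in Bmal1-/-, 5.15% ± 5.70 in Apc+/- and 0.545% ± 0.756 in Dko.

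B cells of Dko were few. Igha, the IgA heavy chain gene, was at 1360 CPM in B cells of Dko against 941 in those of Apc+/- (log2 fold change 0.48 ± 0.09, adjusted p = 0.00826, higher in 3 of 3 libraries; 0.144 without replicate 3), which fell to 0.17 at resolution 2.0 (adjusted p = 0.975) and did not pass with limma voom (0.109) or without the library block (1.0). Plasma cells, which make IgA, were 2.61% of cells in Apc+/- and 14.1% in Dko, and their RNA in B cells was not tested. In CD4 T cells of Dko, the regulatory T list had 0 of 12 members past the threshold over all genes and 4 higher adjusted over the list alone against WT (median 1.125, camera adjusted p = 1.16e-07), and Foxp3 was at 148 against 40.8 CPM in Apc+/- (1.63 ± 0.72, adjusted p = 0.737, higher in 3 of 3 libraries). The class joined clusters 5 and 6, and cluster 6 took 28.5% of it in WT, 43.1% in Apc+/- and 65.3% in Dko. Within cluster 6 Foxp3 was at 1.18 ± 0.86 in Dko against Apc+/- (adjusted p = 0.999). Cytotoxic lymphocytes of Dko had 0 of 11 MHC class II members past the threshold against WT by either adjustment, with a median of -1.89 (camera adjusted p = 1.6e-08). Neither list passed with an estimated correlation. MHC class II genes are markers of B cells, whose transcripts were also counted in cytotoxic lymphocytes.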
